A study of Mus musculus with 18 samples.

How the data were processed

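The series holds RNA sequencing of single GV and MII oocytes from young control, aged control and aged NMN-treated mice, deposited as 18 libraries of 1 oocyte each, 3 per group in 6 groups. Per the labels, each oocyte was lysed gently, the nucleus was pelleted, and the supernatant was used for a library with a TruePrep kit. The authors' notes name FastQC 0.11.8, Trim Galore 0.4.5, TopHat2 2.1.1 and Cufflinks with the builds mm10 and GRCm38. The deposited tables have the column names of an RSEM gene table, a tool the notes do not name, and which step made them is not stated.

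Per the file headers, each table gives an expected count per gene, which was not normalised and was mostly whole numbers. Per the file headers it also gives TPM, which the authors scaled by effective length and library, used here as an alternative. The deposited FPKM values were not used. Each table held the same 47069 gene identifiers. Symbols and GRCm38 coordinates came from GENCODE vM21, which matched 46488 of them, while 581 had no symbol and 118 shared one; genes without a symbol took at most 0.145% of a library's counts.

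A pair of deposited libraries, GV young control 1 and GV young control 2-1, were identical in all 47069 genes and were counted as 1 library, in batch 1. GV aged control 2-2 held 5009 counts in 270 genes, a floor of 599 CPM, and was left out, although the plan had kept every library; its inclusion is an alternative. This left 16 oocytes. Batch was read from the titles, those numbered with a batch 2 prefix being batch 2. The title of MII NMN 2 says batch 2 with no further number, which was read as oocyte 2 of batch 1, and the literal reading is an alternative. The share of detected genes with a fractional count (more than 0.005 from a whole number) was 19.5 to 29.0% in batch 1 and 11.9 to 14.6% in batch 2, and 14.5% in the merged library, which thus resembled batch 2. The 29.0% was that of MII NMN 2, which thus resembled batch 1 and not batch 2.

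The plan fixed before the data were examined was to test each comparison over oocytes with edgeR quasi-likelihood tests, DESeq2 and limma as alternatives, set tests with camera and fry, and permutation tests. These tests were run and their calls were seen. They were then set aside because each library is 1 oocyte and the labels name no animals, so that oocytes of a group are not known to be independent animals. The reason was the unit of replication and not the outcome, and no p-value, standard error or count of called genes is given. The description that takes their place was chosen after the data and those calls had been seen.

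Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10 by group, which left 12161. Counts were scaled to CPM with TMM factors in R 4.3.3. Each group was given by its mean and SD between oocytes, and groups were compared by the log2 ratio of means after adding 1 CPM. Folds given for named genes are plain ratios of the scaled means, without the added 1 CPM. They are therefore larger than the log2 ratios give, most of all where the lower mean is near the floor. Counts pooled over a group carry exact 95% Poisson intervals in unscaled CPM. Where a group had no count, the fold is a lower bound, the scaled mean of the other group over the scaled CPM that 3 counts over the group would give. No interval for a difference between animals can be had. Limma 3.58.1 and DESeq2 1.42.0 served the alternatives, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served tables and figures.

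There were 9 comparisons, age and NMN within each stage, NMN against young controls within each stage, and MII against GV within each condition. The planned interactions between stage and age or NMN were not tested. Genes were named, for the age and NMN comparisons and for maturation in young controls, by a planned rule that was changed after the data had been seen. The p condition was removed. List members, planned to be ranked by smallest p, were ranked by the size of the log2 ratio. The CPM minimum and the absence of overlap, planned for the largest changes, were applied to list members too. The rule used took up to 12 genes per direction with the largest ratio, and up to 4 per list, with at least 10 CPM in the higher group and no overlap between oocytes. It also took genes of NAD synthesis and sirtuins in the NMN comparisons, and Gdf9, Zp3, Btg4, Gapdh and Actb in every group. Predicted genes and pseudogenes were not named, and the text names a part of those that met the rule. Without overlap, chance ordering gives 10% of genes with 3 against 3 oocytes, 20% with 3 against 2 and 33.3% with 2 against 2.

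The 28 gene lists were fixed before the data were examined. They were NAD metabolism, sirtuins, maternal effect genes, oocyte identity and zona genes, spindle checkpoint and kinetochore, cohesin and anaphase control, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, antioxidant enzymes, DNA damage response, maternal mRNA deadenylation and decay, chromatin modifiers, cytosolic ribosomal proteins, proteasome, autophagy and mitochondrial dynamics, glycolysis and pyruvate, citric acid cycle, apoptosis, unfolded protein response, translation initiation and mTOR, microtubule and actin cytoskeleton, immediate early and heat shock genes, nuclear retained RNAs, and markers of cumulus and granulosa, theca and stroma, immune, erythroid and endothelial cells. Lists with at least 5 measured genes were given by the members higher and lower, those equal in both groups counting as neither, by their median log2 ratio, and for a part of them by the percentile of that median among 10000 random lists matched on mean expression in 20 bins, which describes these libraries only. List sums are unscaled CPM over all members. In 40 of the 207 pairs of list and comparison the difference in mean sums had the other sign than the median ratio, and in 15 the mean log2 ratio had.

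The ratios were tested on simulated data, in which every oocyte started from the MII aged control means and genes of the MII NMN oocytes were given known folds. Folds of 0.1, 0.25, 4 and 10 in 50 genes each came out with medians of 0.130, 0.212, 4.04 and 7.20, and with the right direction in 100, 94, 98 and 100% of genes. The 5116 unchanged genes had a median fold of 0.956 with quartiles of 0.574 and 1.60, so folds of that size arise without any change. The lower gene number of the real MII NMN oocytes was not simulated. The correlation of the age and NMN ratios was set against 100 simulations that share the aged control libraries. Alternatives were RLE size factors, no filter, a minimum count of 50, mean TPM, fitted coefficients of edgeR and DESeq2 with several batch terms or a replicate block, libraries of a stage alone, mitochondrially encoded genes left out, and leaving out each oocyte. Library totals, pseudocounts of 10 and 0.1 CPM, each batch alone and the low-count library kept were added after the data had been seen.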

Results

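Gene expression was measured by RNA sequencing in single mouse oocytes at 2 stages of meiosis. Germinal vesicle (GV) oocytes are immature oocytes arrested with an intact nucleus, and metaphase II (MII) oocytes are mature eggs. They came from C57BL/6JAusb females in 3 conditions, which were young controls of 4 weeks, aged controls of 12 months, and aged mice given nicotinamide mononucleotide (NMN), a precursor of the coenzyme NAD, at 2 g/L in drinking water for 4 weeks. The labels name no animals, so each group stood as 1 sample of its condition. No test between groups is given, and the values below describe these oocytes. The groups held 2 GV young control, 2 GV aged control, 3 GV aged NMN and 3 oocytes of each MII condition. Library totals ran from 2756181 to 5586894 counts with a median of 3947706, from 2756181 to 5230045 in GV and from 2842369 to 5586894 in MII oocytes. A floor of 3 counts lay between 0.537 and 1.09 CPM per library, CPM being a library's counts scaled to a common total. Gene values are means of scaled CPM ± SD between the oocytes of a group, and all intervals and floors cover counting error only.

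The oocyte transcripts used as controls were abundant in most groups. Gdf9, a growth factor secreted by the oocyte, was at 955 ± 261, 2658 ± 1257 and 4077 ± 2761 CPM in GV young control, aged control and NMN oocytes. It was at 8603 ± 7628, 3365 ± 3006 and 883 ± 1203 CPM in the same order of MII groups. Zp3, a protein of the zona pellucida, was at 836 ± 77.5, 3462 ± 2877 and 6039.5 ± 4349.7 CPM in GV groups and at 264 ± 104, 319 ± 158 and 23.7 ± 38.0 CPM in MII groups. Btg4, the adaptor that brings the CCR4-NOT deadenylase to maternal mRNAs, was at 581 ± 243, 800.4 ± 532 and 970.4 ± 386 CPM in the GV groups. In the MII groups it was at 2334 ± 1478, 1182 ± 599.7 and 4215 ± 5513 CPM. The housekeeping genes Gapdh and Actb were low. Group means ran from 5.01 ± 6.52 CPM (MII aged control) to 35.8 ± 28.5 CPM (GV aged NMN) for Gapdh and from 2.08 ± 2.60 CPM (MII aged NMN) to 93.5 ± 41.5 CPM (MII young control) for Actb. Marker lists of other cell types served to describe carry-over of somatic cells, which was not told apart from transcripts of the oocyte. Markers of cumulus and granulosa cells summed to 50.6 to 147 CPM in GV oocytes, 156 to 1409 CPM in the 6 MII control oocytes, and 0, 13.1 and 275 CPM in the MII NMN oocytes. Immune markers summed to 8.63 to 258 CPM in GV and 0 to 36.9 CPM in MII oocytes. In the same order, endothelial markers summed to 11.2 to 27.7 and 3.63 to 74.5 CPM, theca and stroma markers to 0 to 8.85 and 0 to 28.3 CPM, and erythroid markers to 0 and 0 to 20.5 CPM.

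The MII oocytes from NMN-treated mice held fewer detected genes than the other 13. They held 6400, 5640 and 7704 genes with at least 1 count, against 9062, 12600 and 13444 in MII young controls, 10394, 10744 and 8515 in MII aged controls, and 8804 to 13756 in GV oocytes. Genes encoded by the mitochondrial genome took 43.0, 33.2 and 6.18% of their counts, against 24.4, 5.08 and 6.55% in MII young controls, 12.6, 10.2 and 9.09% in MII aged controls, and 2.76 to 8.55% in GV oocytes. The first of the NMN oocytes is titled batch 1 and the third batch 2 with a further number. The remaining one, titled batch 2 without a further number, was read as oocyte 2 of batch 1. Its share of fractional counts, 29.0%, resembled batch 1 and argues against the literal reading of its title. Across genes, the median Spearman rho was 0.764 over 14 pairs of oocytes of the same group, 0.736 over 43 pairs of different groups of a stage, and 0.605 over 63 pairs of different stages; genes are not independent replicates. The 3 pairs of MII NMN oocytes were at 0.608, 0.568 and 0.490, and the third of these oocytes was at 0.661 to 0.780 with the 6 MII control oocytes, closer to them than to its own group.

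**Figure D1:**
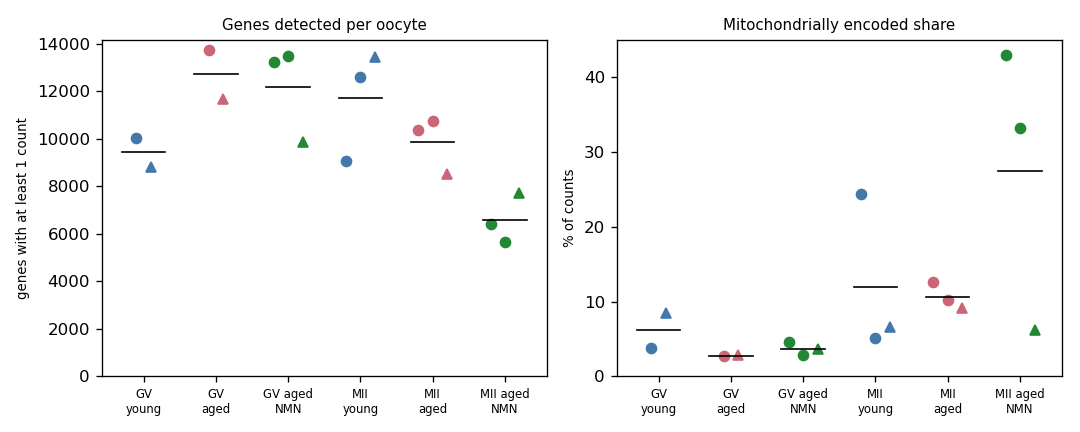
Genes with at least 1 count (left) and percent of counts from mitochondrially encoded genes (right) in each of the 16 oocytes by group, circles for batch 1 and triangles for batch 2. The 3 MII NMN oocytes held 5640 to 7704 genes and the 6 MII control oocytes 8515 to 13444.

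Maturation in young control mice was described by 3 MII against 2 GV oocytes. Per the labels, each library was made from the supernatant over a pelleted nucleus, and MII oocytes hold no nucleus, so these ratios may not compare the same fraction of the cell at both stages. Ribosomal protein mRNAs and nuclear transcripts of oxidative phosphorylation were lower in MII oocytes. Of the 81 cytosolic ribosomal protein genes, 78 were lower and 3 higher, with a median log2 ratio of -3.44. Of the 75 nuclear genes of oxidative phosphorylation 65 were lower and 10 higher (median -3.24). Both medians lay below those of all 10000 random lists of matched expression. Rpl37, a protein of the large ribosomal subunit (ENSMUSG00000041841, GRCm38 chromosome 15, 5116645 to 5119140), was at 6.28 ± 1.94 against 654 ± 218 CPM in MII and GV oocytes, a 104-fold difference. Rps27a, which encodes ubiquitin fused to a small-subunit protein, was at 6.32 ± 1.02 against 629.8 ± 37.0 CPM. Among respiratory chain genes, Cox7c of cytochrome c oxidase was at 13.3 ± 13.7 against 1599.8 ± 276 CPM and Atp5j2 of ATP synthase at 7.93 ± 3.15 against 1225 ± 167 CPM, 120.3-fold and 155-fold lower in MII oocytes.

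Single transcripts moved apart further between these stages. Fcf1, a ribosomal RNA processing factor (ENSMUSG00000021243, GRCm38 chromosome 12, 84970897 to 84983303), was at 17.4 ± 14.8 against 6222 ± 2080.1 CPM, 358-fold lower in MII oocytes. Its pooled counts were 271 and 48094 with 95% Poisson intervals of 15.8 to 20.1 and 6037 to 6146 CPM. Slirp, which stabilises mitochondrial mRNAs, was at 3.57 ± 0.797 against 759 ± 293 CPM, and Snrpd2, a core protein of spliceosomal snRNPs, at 8.98 ± 12.0 against 1611 ± 669 CPM. Genes higher in MII oocytes included Gdf9 (ENSMUSG00000018238, GRCm38 chromosome 11, 53431023 to 53437904), 9.01-fold, and the RNA-binding protein gene Dazl at 2239 ± 1018 against 238 ± 131 CPM. Gdf9 ran from 3678 to 17390 CPM in the MII oocytes, the highest of them carrying much of its fold. Also higher were the cyclin gene Ccnb2 at 669 ± 257 against 100.2 ± 19.2 CPM and Arpc1b of the actin-nucleating ARP2/3 complex at 1230.1 ± 465 against 31.8 ± 38.0 CPM. Btg4 (ENSMUSG00000032056, GRCm38 chromosome 9, 51060901 to 51119875) was 4.01-fold higher, its MII oocytes being at 1428 to 4039.5 CPM, and the poly(A)-binding protein gene Pabpn1l 9.45-fold higher. The zona gene Zp2 was 15.6-fold lower, at 41.1 ± 38.0 against 643 ± 76.1 CPM, and Figla, which switches on zona genes, was at 0.449 ± 0.468 against 76.0 ± 90.5 CPM. Edn1, the endothelin precursor gene, was at 50.1 ± 16.6 CPM in MII oocytes and without a count in GV oocytes, at least 129-fold higher against a floor of 3 counts over the group (0.389 scaled CPM). Gja1, the gap junction protein gene of the cumulus list, was at least 263-fold higher, at 102 ± 92.7 CPM. Whether genes of that list came from the oocyte or from carry-over of somatic cells was not tested.

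Other lists separated the stages less. Of 37 proteasome genes, 25 were lower in MII young oocytes (median log2 ratio -1.20), with Psmb1 of the catalytic core at 27.7 ± 17.7 against 2175 ± 142 CPM. Higher in MII oocytes were 30 of 40 chromatin modifiers (median 1.10) and 11 of 12 cumulus and granulosa markers (1.98). So were 12 of 17 unfolded protein response genes (1.20), such as the endoplasmic reticulum co-chaperone gene Dnajc3 at 1618 ± 926 against 225 ± 211 CPM. The mitochondrially encoded mRNAs had a median of 0.92, with 9 of 13 higher. It was -0.39 within batch 2 and -0.03 without the first MII young oocyte. Each gene named in this comparison had no overlap between its 3 MII and 2 GV oocytes, which chance ordering gives for 20% of genes. The median over all 12161 genes was 0.35 (log2), and 0.10 with RLE size factors, so these ratios stand relative to a shift that depends on scaling.

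Maturation in aged mice, with and without NMN, showed the same lists lower. In aged controls 77 of 81 ribosomal protein genes and 70 of 75 oxidative phosphorylation genes were lower in MII oocytes (medians -3.30 and -2.62). With NMN, 80 and 71 were lower (medians -3.83 and -3.52). Fcf1 was at 30.0 ± 9.06 against 2557 ± 1637 CPM in MII and GV aged control oocytes and at 12.2 ± 21.1 against 2600.4 ± 2384 CPM with NMN. Psmb1 was at 30.3 ± 10.9 against 1139 ± 9.61 CPM and 8.02 ± 13.9 against 1292 ± 589 CPM. Genes of the citric acid cycle had medians of -1.55 in aged controls and -2.83 with NMN, against -0.13 in young controls, where mean TPM gave 0.14. Glycolysis and pyruvate genes had medians of -1.46 and -2.36, against 0.41 in young controls, which was -0.04 within batch 1. Their mean sum in aged controls was not lower, at 17082 CPM in MII against 16967 CPM in GV oocytes. With NMN it was lower, at 4145 against 20920 CPM. Of 25 cohesin and anaphase genes, 19 were higher in MII aged control oocytes (median 0.81). The mitochondrially encoded mRNAs were higher in MII oocytes, with medians of 1.56 in aged controls and 3.10 with NMN, the latter 0.44 within batch 2. The medians of all genes were 0.35 (log2) in young controls, -0.29 in aged controls and -0.82 with NMN. The NMN value was -1.34 without MII NMN 2-1 and -0.02 within batch 2, so a part of these contrasts is a shift of all genes. Whether maturation differed between the conditions was not tested.

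**Figure D2:**
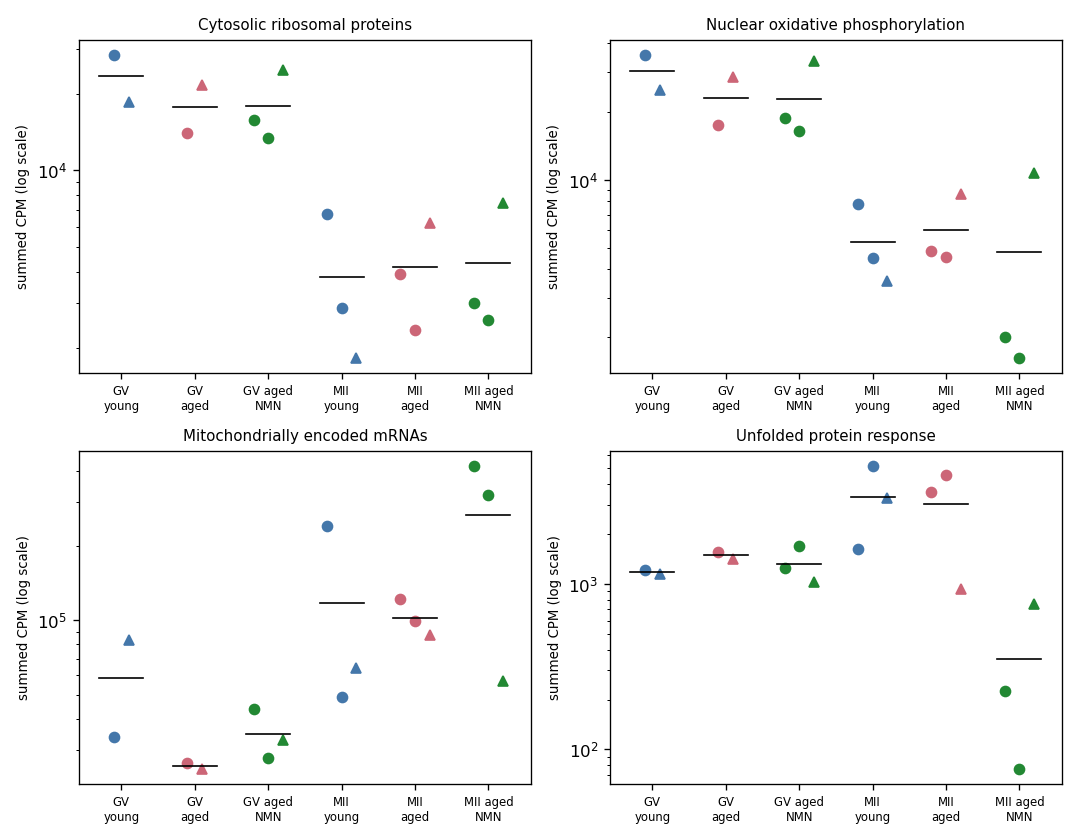
Summed CPM of 4 gene lists in each oocyte by group on log axes, circles for batch 1, triangles for batch 2 and black lines for group means. Ribosomal protein mRNAs summed to 13457 to 28428 CPM in GV and 1823 to 7425 CPM in MII oocytes.

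Age in immature oocytes was described by 2 aged against 2 young control GV oocytes. Mitochondrially encoded mRNAs were lower in aged oocytes, 12 of 13 with a median log2 ratio of -1.33, such as mt-Nd5 of respiratory complex I at 345 ± 1.98 against 1413 ± 15.1 CPM and mt-Nd2 at 897 ± 519.6 against 3018 ± 244 CPM. Ribosomal protein mRNAs were lower for 65 of 81 genes (median -0.47), with Rps27l at 635 ± 461 against 1851 ± 251 CPM. Nuclear oxidative phosphorylation genes were lower for 53 of 75 (median -0.48), although Uqcrc2 of complex III was higher, at 108 ± 9.20 against 22.7 ± 28.1 CPM. Higher in aged GV oocytes were 17 of 23 glycolysis and pyruvate genes (median 1.10) and 22 of 30 cytoskeletal genes (0.70). So were 7 of 7 sirtuins (1.82) and 5 of 6 immediate early and heat shock genes (1.92). GV aged control 1 carried much of the sirtuin difference, with sums of 209 and 55.1 CPM in the aged and 38.9 and 19.3 CPM in the young oocytes, and the sirtuin median was 0.39 without it. The glycolytic aldolase gene Aldoa was at 75.9 ± 29.6 against 17.7 ± 5.15 CPM, Actb at 49.6 ± 15.2 against 13.6 ± 1.89 CPM, and Sirt6, a nuclear deacylase, at 41.7 ± 41.2 against 9.31 ± 3.94 CPM, the aged oocytes being at 70.8 and 12.5 CPM.

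Oocyte genes were among those that differed in the GV stage. Zp3 was 4.14-fold higher in aged oocytes at 3462 ± 2877 against 836 ± 77.5 CPM, and Zp1 3.92-fold higher at 247 ± 53.4 against 62.9 ± 40.3 CPM. Khdc3, of the subcortical maternal complex, was 5.93-fold higher at 1357 ± 1328 against 229 ± 8.67 CPM. GV aged control 1 carried much of these folds, with Zp3 at 5496 CPM in it and 1427 CPM in the other aged oocyte, and Khdc3 at 2296 and 418 CPM. GV aged control 1 is of batch 1 and the other aged oocyte of batch 2. Over GV oocytes of all conditions, the oocyte identity list summed to 12726.6 to 43107.6 CPM in batch 1 (median 41108.4) and 10939.9 to 13727.5 CPM in batch 2. The lowest of batch 1, at 12726.6 CPM, was the merged young library, whose share of fractional counts resembled batch 2. Apart from that library, the oocytes of batch 1 lay far above those of batch 2. Age and batch cannot be told apart for these genes. Sgo1, the shugoshin that protects centromeric cohesin, was 2.72-fold lower, at 39.8 ± 2.06 against 108 ± 20.1 CPM, and Psmb1 lower at 1139 ± 9.61 against 2175 ± 142 CPM. Kctd10, an adaptor of a ubiquitin ligase (ENSMUSG00000001098, GRCm38 chromosome 5, 114363567 to 114380508), was at 85.9 ± 33.6 CPM in aged oocytes from 878 counts and had none in young oocytes, at least 221-fold higher. Igf1, insulin-like growth factor 1 (ENSMUSG00000020053, GRCm38 chromosome 10, 87858265 to 87937042), was at 21.3 ± 2.40 CPM in young oocytes from 164 counts, with an interval of 17.7 to 24.2 CPM and no count in aged oocytes. Against the floor of 3 counts over the aged group, 0.307 scaled CPM, it was at least 69.3-fold lower. Bcl2l15, of the BCL2 family, was lower at 2.37 ± 3.35 against 49.8 ± 3.03 CPM. C1qb, a complement gene of macrophages, was at 118 ± 153 against 1.42 ± 2.00 CPM, the aged oocytes being at 227 and 9.82 CPM, and the immune marker sum was 258 CPM in one aged control oocyte and 16.6 CPM in the other.

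The ribosomal protein median was -1.01 within batch 1 and 0.06 within batch 2, and -0.11 without the first young oocyte. The nuclear oxidative phosphorylation median was -0.81 and -0.06 within the batches. The young oocyte of batch 1 is the merged library, whose share of fractional counts resembled batch 2. With it in batch 2, fitted medians were -0.0839 for ribosomal proteins and 0.0752 for oxidative phosphorylation. Within batches 1 and 2 the median of mitochondrially encoded mRNAs was -0.98 and -1.25, and it was -0.73 without the young oocyte of batch 2. Absence of overlap, which holds for each gene named here, arises for 33.3% of genes by chance ordering of 2 against 2 oocytes. The median of all genes was 0.29 (log2). It was 0.46 with library totals, -0.11 with the aged control library of few counts kept, and 0 without GV aged control 1. Among random lists, the mitochondrially encoded and ribosomal protein lists lay below all, oxidative phosphorylation at percentile 0.01, and the 4 higher lists at 96.7 to 99.8.

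Age in mature oocytes was described by 3 aged against 3 young control MII oocytes. Single cohesin and spindle genes were higher with age. Cenpf of the kinetochore was at 1028 ± 253 against 398 ± 307 CPM, the cohesin loader gene Nipbl at 273 ± 48.3 against 122 ± 90.1 CPM, and Esco2, which acetylates cohesin, at 1397 ± 338 against 834 ± 284 CPM. Of the 25 cohesin and anaphase genes, 14 were higher (median log2 ratio 0.17). That median was -0.20 with mean TPM, and 0.65 and -0.57 within batches 1 and 2. Of the 32 spindle and kinetochore genes, 13 were higher and 19 lower (median -0.08). Lower with age were 21 of 27 antioxidant enzymes (median -0.44), with the superoxide dismutase gene Sod1 at 45.2 ± 14.7 against 139 ± 81.9 CPM and the peroxiredoxin gene Prdx2 at 119.7 ± 21.8 against 275 ± 64.0 CPM. So were 23 of 31 genes of autophagy and mitochondrial dynamics (-0.58). Glycolysis and pyruvate genes were lower for 19 of 23 (median -0.71), although their mean sum was higher, at 17082 against 9978 CPM. Ldha, lactate dehydrogenase A (ENSMUSG00000063229, GRCm38 chromosome 7, 46841475 to 46855627), was at 12.4 ± 9.86 CPM in young and without a count in aged oocytes, at least 51.4-fold lower.

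Maternal effect genes were lower for 17 of 27 (median -0.37), with mean sums of 21249 CPM in aged and 18012 CPM in young controls. Among the lower ones were Zfp57, which maintains imprints, at 35.1 ± 14.5 against 162 ± 46.4 CPM, and Padi6 of the subcortical maternal complex at 83.8 ± 27.3 against 187 ± 11.2 CPM. Actb was 3.76-fold lower, at 24.9 ± 13.9 against 93.5 ± 41.5 CPM. Large differences were in Bdkrb1, a bradykinin receptor gene, at 0.584 ± 1.01 against 35.1 ± 24.5 CPM from 7 and 589 counts, and Cmpk2, a mitochondrial nucleotide kinase gene, at 1.32 ± 1.67 against 36.8 ± 14.4 CPM. In the other direction, Supt6, a transcription elongation factor gene, was at 56.1 ± 31.7 against 4.06 ± 3.03 CPM, and Myh11, smooth muscle myosin heavy chain, at 28.0 ± 10.8 against 2.31 ± 2.38 CPM. Cumulus and granulosa markers were lower for 11 of 12 (median -1.16), their sums being 156 to 266 CPM in aged and 172 to 1409 CPM in young MII oocytes. Whether carry-over of somatic cells differed between these oocytes was not tested. The steroid enzyme gene Hsd3b1 (ENSMUSG00000027871, GRCm38 chromosome 3, 98852194 to 98859794) was at 12.1 ± 0.489 CPM in young and without a count in aged oocytes.

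Mitochondrial and ribosomal lists gave no stable direction with age in MII oocytes. Mitochondrially encoded mRNAs had a median of -0.54, but -1.10 within batch 1, 0.89 within batch 2 and 0.66 without the first young oocyte. The same 3 values were -0.95, 1.01 and 0.44 for ribosomal protein genes, whose median was -0.33. They were -0.63, 1.89 and 1.08 for oxidative phosphorylation genes, whose median was 0.06. The genes named here had no overlap between the groups, which chance ordering gives for 10% of genes with 3 against 3 oocytes. The median of all genes was -0.27 (log2), with 35.5% higher. Among random lists, cohesin genes lay at percentile 97.7, spindle genes at 78.3, antioxidant enzymes at 18.9, maternal effect genes at 12.0, autophagy genes at 6.05, glycolysis genes at 4.14 and cumulus markers at 0.53.

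NMN in immature oocytes of aged mice was described by 3 treated against 2 control GV oocytes. Mitochondrially encoded mRNAs were higher with NMN for 12 of 13 (median log2 ratio 0.63, and 0.68 and 0.54 within batches 1 and 2). In this list, mt-Nd5 was at 616 ± 245 against 345 ± 1.98 CPM and the cytochrome b gene mt-Cytb at 17885 ± 5345 against 10656 ± 4023 CPM. Proteasome genes were higher for 31 of 37 (median 0.35), with Psma5 at 297 ± 41.8 against 185 ± 81.6 CPM. Ribosomal protein genes were higher for 70 of 81 (median 0.27). Nuclear oxidative phosphorylation genes were higher for 55 of 75 (median 0.25, turning to -0.01 with library totals). The cytochrome c oxidase genes Cox4i1 and Cox6a1 were at 845 ± 177 against 482 ± 192 CPM and at 363 ± 33.8 against 233 ± 11.8 CPM. Lower with NMN were 22 of 31 genes of maternal mRNA decay (median -0.27), such as Pan3 of a deadenylase complex at 28.3 ± 17.6 against 98.1 ± 33.1 CPM and the m6A reader gene Ythdf2 at 17.0 ± 4.76 against 59.8 ± 48.4 CPM, aged controls being at 25.6 and 94.0 CPM.

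Chromatin and DNA repair genes were lower in NMN GV oocytes for 28 of 40 and 26 of 37 (medians -0.21 and -0.28). The chromatin remodeller gene Smarca4 was at 25.3 ± 0.554 against 48.1 ± 7.00 CPM and the demethylase gene Kdm1a at 9.37 ± 3.99 against 32.4 ± 9.67 CPM. Dnmt3l, a cofactor of DNA methylation in oocytes, was higher at 62.9 ± 22.1 against 27.9 ± 0.941 CPM. Birc5, the survivin gene, was 1.50-fold higher at 2158 ± 297 against 1442 ± 142 CPM, and Pttg1, securin, 1.38-fold higher at 3333 ± 623 against 2411 ± 80.8 CPM. Both folds lay between the quartiles of unchanged genes, 0.574 and 1.60, in the simulated MII comparison. Igf1 was at 13.6 ± 16.0 CPM from 120 counts with NMN and without a count in aged controls. GV NMN 2-1 held most of it, at 31.9 CPM, and the other NMN oocytes were at 6.40 and 2.44 CPM. Ciao2a, of the cytosolic iron-sulfur assembly machinery, was 5.24-fold higher at 32.5 ± 5.12 against 6.19 ± 5.63 CPM, and Coq2, of coenzyme Q synthesis, 9.58-fold lower at 2.67 ± 2.33 against 25.6 ± 16.3 CPM.

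Of the genes of NAD metabolism in GV oocytes, 7 of 12 measured were higher and 5 lower with NMN. Their median was 0.09, turning to -0.07 with library totals and -0.06 with mean TPM. Their sum was lower with NMN in each oocyte, at 164 to 176 against 212 and 215 CPM. Nampt, which makes NMN, was at 6.74 ± 6.25 against 6.42 ± 8.04 CPM, Nmnat1, which turns NMN into NAD, at 22.0 ± 9.43 against 12.5 ± 8.33 CPM, and Nmrk1, the nicotinamide riboside kinase gene, at 39.2 ± 12.0 against 56.1 ± 39.0 CPM. The NAD kinase gene Nadk was 3.24-fold lower at 8.15 ± 1.43 against 26.4 ± 8.83 CPM, and the NAD-dependent deacylases Sirt1 and Sirt3 were at 5.80 ± 5.96 against 14.5 ± 12.5 CPM and 16.2 ± 14.0 against 2.72 ± 3.84 CPM. Sirtuins as a list had a median of 0.64, which was -0.12 within batch 2. Apart from Nampt, Nmnat1, Nmrk1, Sirt1 and Sirt3, named whatever their overlap, each gene named for this comparison had no overlap, which chance ordering gives for 20% of genes. The median of all genes was 0.01 (log2). Among random lists, mitochondrially encoded mRNAs lay above all, proteasome, ribosomal and oxidative phosphorylation genes at percentiles 99.7, 99.8 and 97.9, sirtuins at 97.4 and NAD metabolism at 68.5. Decay, chromatin and DNA repair genes lay at 0.65, 3.31 and 2.28. Maternal effect genes, lower for 16 of 27 (median -0.22), lay at 0.02, with a median of 0.04 within batch 1 and 0.37 with the aged control library of few counts kept. With the aged control library of few counts kept, the median of all genes was 0.49, and the decay, chromatin and DNA repair lists turned to 0.27, 0.32 and 0.24.

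NMN in mature oocytes of aged mice was described by 3 treated against 3 control MII oocytes. Genes of the unfolded protein response were lower with NMN for 14 of 17 (median log2 ratio -2.02, below all 10000 random lists). Their sums were 225, 75.9 and 750 CPM in the 3 NMN oocytes against 931 to 5129 CPM in the 6 MII controls. Pdia3, a disulfide isomerase of the endoplasmic reticulum (ENSMUSG00000027248, GRCm38 chromosome 2, 121413775 to 121438687), had no count in the NMN oocytes (floor 0.335 scaled CPM) and was at 124 ± 115 CPM in aged controls from 1875 counts, at least 369.7-fold lower. Dnajc3 (ENSMUSG00000022136, GRCm38 chromosome 14, 118937976 to 118981697) was 15.3-fold lower, at 101 ± 126 against 1552 ± 1190.1 CPM. Sel1l, of endoplasmic reticulum degradation, was 44.4-fold lower at 0.756 ± 0.988 against 33.6 ± 9.64 CPM, and the stress sensor gene Atf6 12.4-fold lower at 3.44 ± 5.95 against 42.6 ± 14.2 CPM. Mitochondrially encoded mRNAs were higher for 13 of 13 (median 1.97), with mt-Co3 (ENSMUSG00000064358, GRCm38 chromosome M, 8607 to 9390) at 2599.9 ± 1495 against 232 ± 401 CPM. The SD of mt-Co3 in aged controls exceeded its mean, so a single oocyte held most of the counts there.

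Most oocyte transcripts were lower in the NMN MII oocytes. Maternal effect genes were lower for 22 of 27 (median -1.07) and oocyte identity and zona genes for 19 of 22 (median -1.21). H1foo, the oocyte linker histone (ENSMUSG00000042279, GRCm38 chromosome 6, 115944938 to 115950236), was 5.22-fold lower at 4117 ± 6445 against 21495 ± 9825 CPM, from 39304 against 252176 counts. Zp3 (ENSMUSG00000004948, GRCm38 chromosome 5, 135980099 to 135988624) was 13.5-fold lower at 23.7 ± 38.0 against 319 ± 158 CPM, and Padi6 14.9-fold lower at 5.61 ± 5.21 against 83.8 ± 27.3 CPM. The NMN oocytes ran from 0 to 67.5 CPM for Zp3, so the size of its fold rests on the highest of them. Khdc3 was 6.85-fold lower at 20.5 ± 27.1 against 140.3 ± 35.8 CPM, and the maintenance DNA methyltransferase gene Dnmt1 4.49-fold lower at 83.5 ± 143 against 374 ± 72.4 CPM. Sums of the maternal effect list were 10799, 15047 and 44643 CPM in the 3 NMN oocytes and 12139 to 32186 CPM in the 6 MII controls, so that their mean was not lower with NMN (23496 against 21249 CPM in aged controls). Sums of the oocyte identity list were 3428, 2732 and 20663 CPM in the 3 NMN oocytes and 17346 to 70232 CPM in the 6 MII controls. Btg4 went the other way, at 4215 ± 5513 against 1182 ± 599.7 CPM, with overlapping oocytes, MII NMN 2 being at 10564 CPM and the other NMN oocytes at 1444 and 638 CPM.

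Cell division and cytoskeletal genes were lower in NMN MII oocytes for 27 of 30 cytoskeletal genes (median -0.93) and 22 of 32 spindle and kinetochore genes (-0.61, and 0.18 within batch 2). Over all genes only 32.3% were higher in this comparison, so the spindle count was near the share over all genes. Kif11, the spindle motor, had no count with NMN and was at 22.7 ± 6.19 CPM in aged controls, at least 67.8-fold lower. The spindle protein gene Tacc3 was at 9.05 ± 12.8 against 178 ± 133 CPM and the checkpoint gene Bub3 at 73.3 ± 64.4 against 239 ± 102 CPM, while Nuf2 of the kinetochore was 3.13-fold higher at 210.3 ± 76.9 against 67.3 ± 21.7 CPM. Gmps, GMP synthase, was 349-fold lower at 0.729 ± 1.26 against 254 ± 208 CPM. Its NMN mean was near the floor of 3 counts per library and below its SD, so the size of this fold is uncertain. Higher with NMN were the splicing factor gene U2af1l4, 21.2-fold at 1076 ± 778 against 50.8 ± 28.4 CPM, and the long noncoding RNA Pvt1 at 107 ± 81.3 against 3.91 ± 4.26 CPM. So were the translation factor genes Eif4e and Eif1 at 169 ± 111 against 39.3 ± 3.85 CPM and 186 ± 14.7 against 66.0 ± 35.5 CPM, the apoptosome gene Apaf1 at 27.2 ± 2.33 against 7.49 ± 2.99 CPM, and Bdkrb1 at 32.9 ± 13.1 against 0.584 ± 1.01 CPM. DNA damage response genes were lower for 28 of 37 (median -1.11), citric acid cycle genes for 17 of 20 (-1.07) and ribosomal protein genes for 59 of 81 (-0.64, with mean sums of 4338 against 4159 CPM). The size of the ribosomal protein median depended on single oocytes, and it lay much lower without MII NMN 2-1, as given below. In NAD metabolism, 9 of 12 genes were lower (median -0.58), with Nmrk1 at 70.4 ± 33.3 against 74.4 ± 25.4 CPM and Nmnat1 at 7.52 ± 7.17 against 11.5 ± 1.59 CPM. Parp2, an NAD-consuming DNA repair enzyme, was 8.32-fold lower at 4.06 ± 6.76 against 33.8 ± 13.0 CPM, and Nampt was at 0 and 1.30 ± 1.32 CPM.

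The differences between lists were larger within batch 1. Within batch 1 and batch 2, with 1 NMN oocyte in the latter, the unfolded protein response median was -2.85 and -0.49, and that of mitochondrially encoded mRNAs 2.57 and -0.64. That of maternal effect genes was -2.63 and -0.13, and that of oocyte identity genes -2.49 and -0.17. With the titles read literally, another NMN oocyte falls in batch 2, although its share of fractional counts resembled batch 1. Fitted medians of the unfolded protein response and mitochondrially encoded lists were then -2.29 and 1.99. Except for Btg4, Nmrk1, Nmnat1 and Nampt, the genes named here had no overlap between the 3 NMN and 3 aged control oocytes, which chance ordering gives for 10% of genes. The median of all genes was -0.33 (log2). It was -0.64 with library totals, -0.71 without MII NMN 2-1, and 0 within batch 2. Among random lists, mitochondrially encoded mRNAs lay above all, and maternal effect and oocyte identity genes both at percentile 0.11. Cytoskeletal genes lay at 1.22, DNA damage response at 1.25, citric acid cycle at 2.85, ribosomal proteins at 3.49, spindle genes at 12.2 and NAD metabolism at 45.1.

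**Figure D3:**
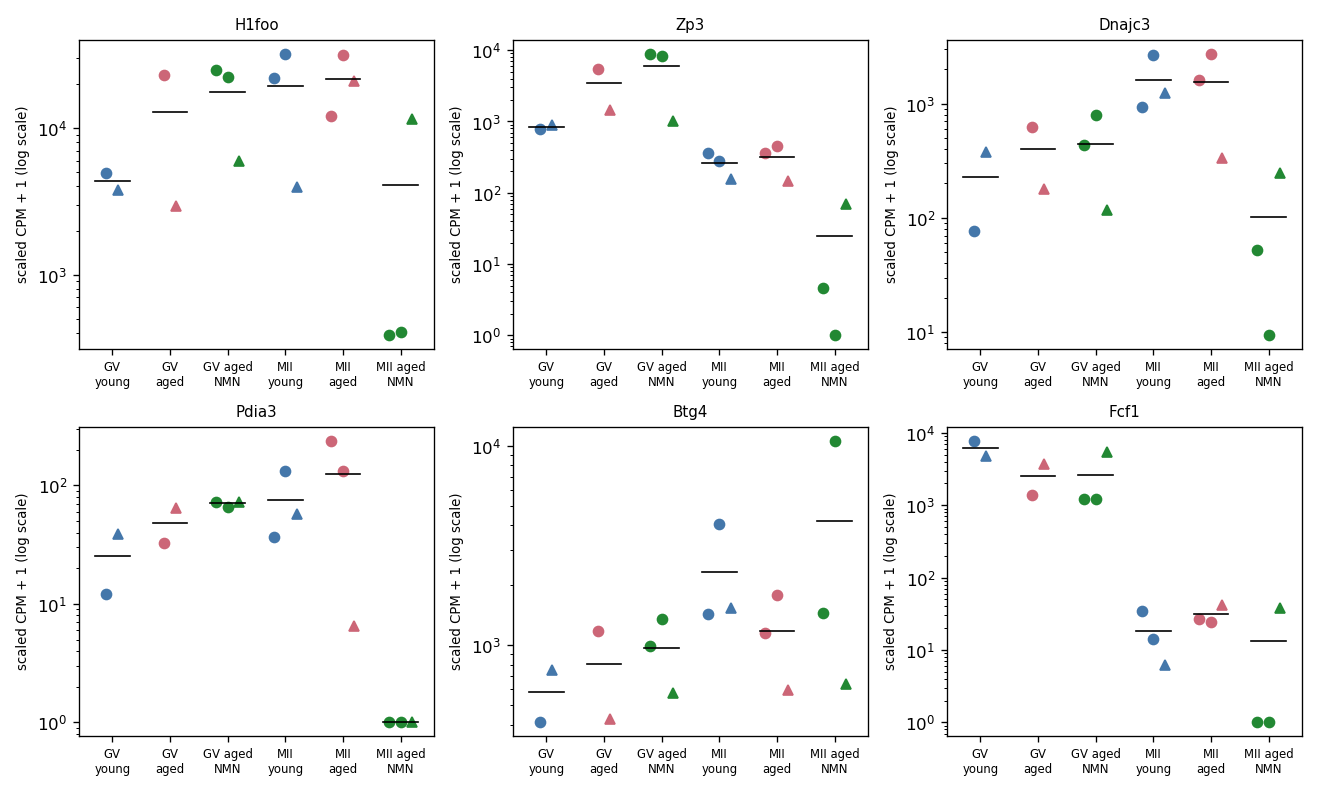
Scaled CPM plus 1 on a log axis for H1foo, Zp3, Dnajc3, Pdia3, Btg4 and Fcf1 in each oocyte by group, circles for batch 1, triangles for batch 2 and black lines for group means. Pdia3 had no count in the 3 MII NMN oocytes, and Fcf1 was at 6222 ± 2080.1 CPM in GV and 17.4 ± 14.8 CPM in MII young control oocytes.

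Treated aged oocytes were also set against young controls. In GV oocytes, glycolysis and pyruvate genes were higher with NMN (median log2 ratio 1.55), as were sirtuins (2.51) and antioxidant enzymes (0.99). Within batch 2 these medians were 0.54, 0.68 and 0.27. The sirtuin sum was 34.8 CPM in GV NMN 2-1, 198 and 181 CPM in the other NMN oocytes, and 38.9 and 19.3 CPM in young controls. The antioxidant sum was 1992 CPM in GV NMN 2-1, 5482 and 4617 CPM in the others, and 1724 and 1863 CPM in young controls. Immediate early and heat shock genes (median 1.31, mean sums of 536 against 153 CPM) and immune markers (mean sums of 97.6 against 8.87 CPM) were higher in the same oocytes. Genes of maternal mRNA decay were lower for 22 of 31 (-0.55), with mean sums of 3445 against 3104 CPM. Mitochondrially encoded mRNAs were below young controls for 12 of 13 (median -0.42, against -1.33 in untreated aged oocytes), with mt-Nd5 at 616 ± 245 against 1413 ± 15.1 CPM. Without GV young control 2-2 that median was -0.12, the sums being 33721 and 83532 CPM in the young and 27664 to 43957 CPM in the NMN oocytes. In MII oocytes, 15 of 17 unfolded protein response genes (-2.43), 23 of 27 maternal effect genes (-1.39) and 12 of 12 cumulus and granulosa markers (-2.14) were lower with NMN than in young controls. The mean sum of maternal effect genes was higher with NMN, at 23496 against 18012 CPM. At this stage 13 of 13 mitochondrially encoded mRNAs were higher with NMN (1.58, and -0.03 within batch 2). The unfolded protein response median was -4.20 and -1.90 within batches 1 and 2. The medians of all genes were 0.26 in GV and -0.68 in MII oocytes.

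The question of whether NMN moved genes against the difference with age was addressed across all genes, which are not independent replicates. The log2 ratios for age and for NMN had a Pearson r of -0.236 in GV and -0.282 in MII oocytes. Since the aged controls enter both ratios with opposite sign, a negative value arises without any effect: 100 simulations of unchanged groups gave -0.541 (-0.558 to -0.525) in GV and -0.499 (-0.520 to -0.481) in MII oocytes. The observed covariance exceeded the simulated one by 0.835 in GV and 0.179 in MII oocytes. The correlation was thus weaker than the simulations gave. In GV oocytes the simulated covariance was -1.11 (-1.17 to -1.05) against -0.273 observed, and in MII oocytes -0.605 (-0.656 to -0.560) against -0.426. Whether the simulated spread between oocytes matched the real one was not tested, and a spread set too wide would hide an opposition. The simulations can therefore not decide whether NMN opposed age across genes. Genes that lay on opposite sides included Igf1 in GV oocytes, which with NMN was mostly in GV NMN 2-1, and Bdkrb1 in MII oocytes, both given above with their counts.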

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

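The tests of sequencing depth, of counts taken by mitochondrial genes, of a further course of maturation and of loss blind to the gene were chosen after the result was seen, and the bounds for batch and transcript length were set before.

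The summed CPM of the genes of autophagy and mitochondrial dynamics differed with age in opposite directions at the 2 stages. It was 394 CPM higher in aged than in young control GV oocytes, and the aged minus young difference was -779 CPM in MII oocytes, with every aged oocyte above every young one in GV and below in MII. The list was flagged by that same rule, no overlap in opposite directions at the 2 stages. It was applied, for age and for NMN, to every list sum, the mitochondrial share and the number of detected genes. Chance ordering gives no overlap for 33.3% of genes with 2 against 2 oocytes and 10% with 3 against 3. The separation itself is therefore no support. In TPM the MII groups overlapped, with aged controls at 937 to 1408 and young controls at 1375 to 3321. The list medians lay at percentiles 76.7 in GV and 6.05 in MII of the random lists, beside medians over all genes of 0.29 and -0.27 (log2). The difference between the stages was not tested.

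The MII NMN oocytes held 5640 to 7704 detected genes and the 6 MII control oocytes 8515 to 13444. With each MII library thinned to 2842358 counts, the highest NMN minus the lowest control oocyte was -884 genes, and with mitochondrially encoded genes left out and 1878212 counts kept it was -895, which argues against sequencing depth and against counts taken by mitochondrial genes as the whole cause. With abundance in MII aged controls held fixed, the NMN ratio did not go with the young maturation ratio across genes (partial Spearman rho -0.0271). That abundance also enters the NMN ratio, and genes already low in MII oocytes can fall little further. The rho therefore does not decide on a further course of the maturation change. The unfolded protein response list lay at percentile 0.01 of 10000 random lists matched on abundance in the MII controls, but it had been picked because its median was the lowest of the 23 lists, so this value does not decide on a loss blind to the gene. That loss, a further course of the maturation change and NMN treatment may each contribute and stay open as hypotheses. So may the condition or lysis of these oocytes and the batch to which the lowest 2 were assigned.

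GV oocytes differed between batches in a way that recurred. Over genes, batch 1 minus batch 2 in aged controls correlated with the same difference in NMN oocytes, which share no library with them (Pearson r 0.365, 0.3 having been set beforehand), consistent with a difference between batches. The ratio of aged to young GV oocytes correlated with the batch difference in NMN oocytes at r 0.274, between the bounds of 0.1 and 0.3, so that age and batch cannot be told apart for these genes. With 2 oocytes per group, and the merged young library labelled with both batches, no value decided between them, and age itself stays open.

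Ribosomal protein mRNAs were lower in MII than in GV oocytes in all 3 conditions. Their median transcript length was 711 bases against 1993 over all genes, and longer transcripts had higher ratios (Spearman rho over genes 0.243, 0.234 and 0.195 in young control, aged control and NMN oocytes). Transcript length was used where effective length had been planned. Random lists matched on length and on abundance in GV oocytes had medians between -2.04 and -1.55. The list lay below all of them in each condition (percentile 0), by -1.40, -1.74 and -1.82 from those medians. Abundance in GV oocytes also enters the ratio, so the low medians of the matched lists cannot be credited to length alone. The position of the list below all of them argues against length as the whole cause, and the share due to length was not tested. A lower amount of these mRNAs may account for the rest, as may a shortening of their poly(A) tails that lowers capture, which was not tested.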

How the results depend on the processing

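The batches taken alone, the low-count library, library totals and the pseudocounts were added after the data had been seen. Values are median log2 ratios of 4 lists, and where an alternative moved one the cause was not tested. Taken alone, batch 2 gave, for age in GV oocytes, -0.0603 for nuclear oxidative phosphorylation and 0.0635 for ribosomal proteins, for which batch 1 gave -1.01. For age in MII oocytes it gave 0.89 for mitochondrially encoded mRNAs, 1.89 for oxidative phosphorylation, 1.01 for ribosomal proteins and -0.94 for the unfolded protein response. For NMN in MII oocytes it gave -0.64 for mitochondrially encoded mRNAs and -0.49 for the unfolded protein response, and for young maturation -0.39 for mitochondrially encoded mRNAs. The unfolded protein response in GV NMN oocytes (main value 0.16) had no stable sign. It was -0.0499 and -0.15 in batches 1 and 2, -0.0185 with library totals, -0.0296 with a batch term and -0.0748 with the batch titles read literally. With a batch term in DESeq2, that list was 0.0262 for age in MII oocytes.

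Of 31 pairs of oocytes with equal replicate number, 10 correlated above 0.1 (median 0.0624, from -0.120 to 0.365). Pairs of unequal number were not computed, and numbers with a batch 2 prefix occur only in batch 2. Whether the numbers pair the oocytes can therefore not be decided. With the numbers as a replicate block, GV age medians were -0.67 for mitochondrially encoded mRNAs, -0.95 for oxidative phosphorylation and -0.99 for ribosomal proteins. Ribosomal proteins were 0.72 for GV NMN and the unfolded protein response 0.27 for young maturation under that replicate block. With the identical library in batch 2, oxidative phosphorylation was 0.0752 and ribosomal proteins -0.0839 for GV age, and ribosomal proteins -2.60 for young maturation. With the low-count library kept, oxidative phosphorylation was -1.07 and ribosomal proteins -1.01 for GV age. For GV NMN it gave 1.17 for mitochondrially encoded mRNAs, 0.81 for oxidative phosphorylation, 0.85 for ribosomal proteins and 0.69 for the unfolded protein response. Ribosomal proteins were -0.0901 for GV age with mean TPM and -2.48 for young maturation with a pseudocount of 10 CPM.

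Leaving out 1 oocyte at a time gave -1.49 to -0.73 for mitochondrially encoded mRNAs and -0.85 to -0.11 for ribosomal proteins in GV age, the upper ends being without GV young control 2-2 and without GV young control 1. For MII age the ranges were -0.90 to 0.66 and -0.64 to 0.44, the upper ends without MII young control 1. The range was -0.0528 to 0.34 for the unfolded protein response in GV NMN, -2.36 to -0.19 for ribosomal proteins in MII NMN, the lower end without MII NMN 2-1, and -0.0313 to 1.29 for mitochondrially encoded mRNAs in young maturation, the lower end without MII young control 1.

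Over all 207 list medians, 591 of 4956 values under alternatives moved by more than the spread between oocytes and 435 had the other sign. For the 448 named gene ratios, 1885 of 10664 moved and 53 had the other sign, and 270 of the 448 moved over 1.5 times when 1 oocyte was left out. Of 30 group sums of other-cell lists, 10 moved by more than their SD with TPM in place of CPM. The low counts of GV aged control 2-2 left a floor of 599 CPM. The planned fits without robust dispersion, the camera test with an estimated correlation, fry, the limma test on TPM and the counts of called genes have no value without a test over oocytes and are not given, mean TPM taking the place of the limma test.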

Other observations

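No test was run for the values in this part, which were chosen for description after the data had been seen.

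Translation initiation and mTOR genes had median log2 ratios of 0.36 for MII against GV young controls, -0.11 and -0.19 for age in GV and MII oocytes, and 0.02 and -0.43 for NMN, of which the maturation median turned to -0.57 within batch 2, the GV age median to 0.10 with library totals and the GV NMN median to -0.22. For age in MII oocytes their mean sum was higher, at 8566 against 5539 CPM. Eif5b, which joins the ribosomal subunits, was at 422 ± 186 against 864 ± 30.8 CPM in aged and young GV oocytes and at 1091 ± 335 against 476 ± 273 CPM in MII oocytes. Apoptosis genes had medians of 0.72, 0.78, -0.41, 0.20 and 0.00 in the same order, with -0.87 for maturation within batch 2 and -0.04 for GV NMN with mean TPM. The cytochrome c gene Cycs was at 238 ± 294 against 2034 ± 875 CPM in MII and GV young oocytes and at 1043 ± 457 against 2034 ± 875 CPM in aged and young GV oocytes.

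Nuclear retained RNAs summed to 8.31 to 354 CPM in GV and 27.7 to 1216 CPM in MII oocytes. Per the labels the nucleus was pelleted from each lysate, and whether this acted alike on GV oocytes, which hold one, and MII oocytes, which do not, was not tested. Malat1 was at 1395, 18.8 and 57.5 CPM in the 3 MII young controls and at 0.772 and 18.8 CPM in the GV young controls, so that a single oocyte held most of it. Immediate early and heat shock genes summed to 69.3 to 653 CPM in GV and 31.6 to 180 CPM in MII oocytes, with the phosphatase gene Dusp1 at 44.1 ± 26.6 against 2.48 ± 3.14 CPM in MII and GV young controls. The cohesin and anaphase list had medians of -0.05 for age in GV oocytes, 0.15 with library totals, and -0.47 for NMN in MII oocytes. Cdk1, the kinase of meiotic entry, was at 8.30 ± 11.7 against 62.9 ± 14.1 CPM in MII and GV young controls.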
